A study of Homo sapiens with 6 samples.

How the data were processed

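ATAC-seq libraries of A549 cells were compared in 2 groups, 3 control libraries and 3 with an introduced ZNF296 reading frame. Groups and replicate numbers came from the sample titles. The deposited files were 6 peak lists, 1 per library, in the narrowPeak layout, with no sign of pooling. Per the submitters' processing notes, Trim Galore 0.6.7, Bowtie2 2.4.5 and MACS2 2.2.7.1 were used with GRCh38/hg38. Their roles and settings, including any shift of read ends for the transposase, removal of duplicates or of mitochondrial reads, and the effective genome size, are not given in the sources used here.

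Each deposited peak carried a fold enrichment, a ratio of pileup to local background with 1 added to each. Where the background is low, this ratio therefore also depends on depth. Each also carried the −log10 of its p-value and of its q-value, as deposited, and the distance of its summit from its start. The deposited score was tested to be the whole part of 10 times the −log10 q-value in every list. The lowest −log10 q-value was close to 2 in each deposited list, so peaks had been kept at q under 0.01. Fold enrichments and q-values were used to rank or filter peaks within their own list, and fold enrichments and p-values to recover pileups and depths, which were compared between libraries. No interval occurred more than once in a list.

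No read totals were used here. They were recovered instead, because in these lists fold enrichment and p-value follow from a whole-number summit pileup and a Poisson background. For each whole pileup the background was set to meet the fold enrichment exactly. The −log10 p-value was then matched within 0.001 for at least 99.9% of peaks in every list. The most frequent background gave the library floor, and the spacing of the backgrounds gave the mean fragment length, 207.5 to 237.0 bases. Fragment totals follow from these for an assumed genome size of 2700 Mb, so only their ratios are independent of that assumption. On simulated values the pileup was recovered for 99.98% of 4999 peaks. The simulated backgrounds did not reach down to the floor of control replicate 2. Intervals on shares cover counting error only.

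Peaks on chromosomes 1 to 22, X and Y were merged across libraries where they overlapped by at least 1 base. A region was ZNF296-only with a peak in 3 of 3 ZNF296 and 0 of 3 control libraries, control-only in the opposite case, and mixed when any other 3 libraries held it. Tested on 20000 simulated regions at the recovered depths, 4-fold changes were called for 33.0% (higher with ZNF296) and 16.0% (higher in control) of 200 regions each, and 8-fold changes for 51.5% and 38.0%. Part of the simulated regions, changed and unchanged, were given lowered pileups, so these shares depend on that setting as well as on the depths. Of 19200 unchanged simulated regions, 0.781% were called ZNF296-only and 0.068% control-only, an imbalance whose direction is due to the depths alone.

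Genes were the 20037 protein-coding genes of the RefSeq table for GRCh38.p14. That table gives the start and end of a gene without its strand or exons. The windows planned around transcription start sites were therefore replaced by windows of 1000 bases on each side of both annotated gene ends, and the statements on exons and introns that were planned for ZNF296 were not made. Regions were assigned to the nearest gene end within 100000 bases. The planned search for 26 motifs needs genome sequence and was not run.

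Group means were compared by exact two-sided permutation over 20 label assignments, and list similarity by exact one-sided permutation over 10 splits, with 0.1 the smallest p in each. Gene lists (22, with 736 of 738 symbols matched) were fixed before the data were examined. For gene ends, the mean difference in the number of libraries with a peak was ranked among 10000 random lists matched on the number of libraries. For regions, Fisher's exact test compared ZNF296-only with control-only counts. Both were adjusted by the Benjamini-Hochberg method over the 22 lists.

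Named genes followed a rule set beforehand: ZNF296 and 15 immune genes (some of them not reported here), list members with group-specific gene ends (at most 12 per direction), and the 10 genes and 5 regions per direction with the highest ranks, ranked by the lowest percentile of the −log10 q-value over the libraries of the group. Alternatives set beforehand were stricter peaks (−log10 q-value or fold enrichment of at least 5), equal numbers of peaks, peaks reduced to 100 bases on each side of their summits, an asymmetric threshold, windows of 500 and 2500 bases, leaving out each library, and a replicate block. Alternatives added after the data were seen were matched depth, in which summit pileups were thinned at random to the depth of control replicate 2 and kept above that library's lowest −log10 p-value (20 draws, the first used for single values), matched depth without control replicate 2, matched depth without each library in turn (for the balance and the location of ZNF296-only regions, thinned to the shallowest library left), and coverage of at least 50% of a region. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.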

Results

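Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in A549 cells, a human lung adenocarcinoma line. There were 3 control libraries and 3 libraries of cells into which a ZNF296 open reading frame had been introduced. ZNF296 encodes a C2H2 zinc finger protein. The series title places the study in immune evasion by epithelial cancer cells, and the design asks which accessible sites depend on ZNF296. The labels do not state what the control cells carried, so the groups may also differ in the vector or its delivery. Each library had its own list of peaks, with GRCh38 coordinates. Nothing in the labels states that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The depth recovered from the peak values was 7.17, 2.91 and 5.38 M fragments (M, mega) in control replicates 1, 2 and 3, and 6.39, 6.95 and 7.89 M in ZNF296 replicates 1, 2 and 3. Control replicate 2 was thus the shallowest library.

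The first comparison examined the ZNF296 gene itself, at chromosome 19, 45071500 to 45076478. All 3 ZNF296 libraries had a peak inside the gene near its low-coordinate end (region 45071617 to 45072554), and none of the 3 control libraries did. Its fold enrichment over local background was 11.9 ± 0.608 (SD, n = 3), and in the ZNF296 lists it ranked between the 99.55th and the 99.88th percentile by q-value. A different region of the gene, bounded by 45075285 and 45075912, held a peak in 3 of 3 control libraries (fold enrichment 8.49 ± 0.203, SD, n = 3) and in 0 of 3 ZNF296 libraries. A peak at the high-coordinate end of ZNF296 was present in 3 of 3 ZNF296 libraries and 1 of 3 control libraries. The local background at the low-coordinate peak was 25.6 to 26.8 times the library floor in the ZNF296 libraries, and at the control-only peak it was 12.7 to 13.9 times the floor in the control libraries; these backgrounds can include reads of the peaks themselves. Fold enrichments here and below are the authors' values for each peak and rank peaks only within their own list. Peaks at this gene can hold reads from the introduced reading frame.

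**Figure D1:**
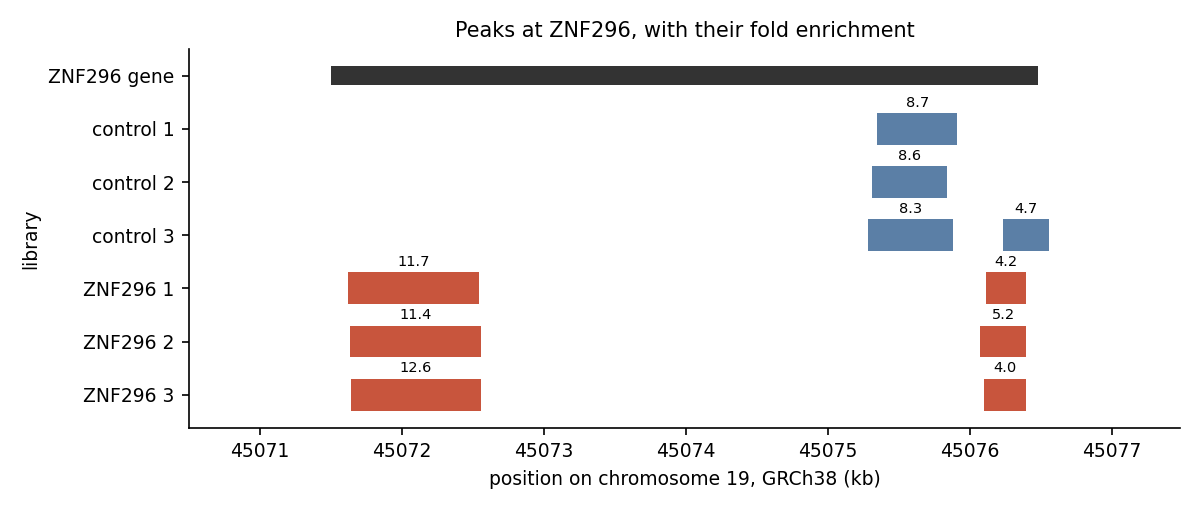
Peaks at ZNF296 in each library, drawn to scale on chromosome 19 (kilobases, GRCh38), with the gene as a black bar and each peak's fold enrichment printed above it. The peak near the low-coordinate end is in the 3 ZNF296 libraries, and the one between 45075285 and 45075912 is in the 3 control libraries.

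Over chromosomes 1 to 22, X and Y, the ZNF296 libraries held 50020 ± 3839 peaks and the control libraries 37362 ± 7262 (SD, n = 3 each), a ratio of 1.34. Every ZNF296 list was longer than every control list (46183 to 53861 against 29254 to 43267). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. At matched depth, with every library thinned to the depth of control replicate 2 (a setting chosen after the data were seen), the means were 36965 ± 779 and 32148 ± 2508 (SD, n = 3 each), a ratio of 1.15, and the difference dropped from 12658 to 4817 peaks. Peaks lying within 1000 bases of either annotated end of a protein-coding gene made up 24.2% ± 1.24 of the ZNF296 lists and 30.7% ± 2.46 of the control lists (SD, n = 3 each; exact two-sided permutation p = 0.1). This difference was -6.45 percentage points, and -2.24 with equal numbers of peaks per list. Peaks covered 24.2 ± 2.93 Mb in ZNF296 libraries and 17.6 ± 5.67 Mb in control libraries (exact two-sided permutation p = 0.3, n = 3 each), and the difference of 6.54 Mb was 3.52 Mb without control replicate 2. The recovered depths also overlapped between the groups (exact two-sided permutation p = 0.3, n = 3 each). The lists resembled each other more within groups (mean Jaccard index of covered bases 0.500) than between groups (0.390), and none of the other 9 splits of the libraries gave a larger difference (exact one-sided permutation p = 0.1, the smallest possible with 10 splits).

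**Figure D2:**
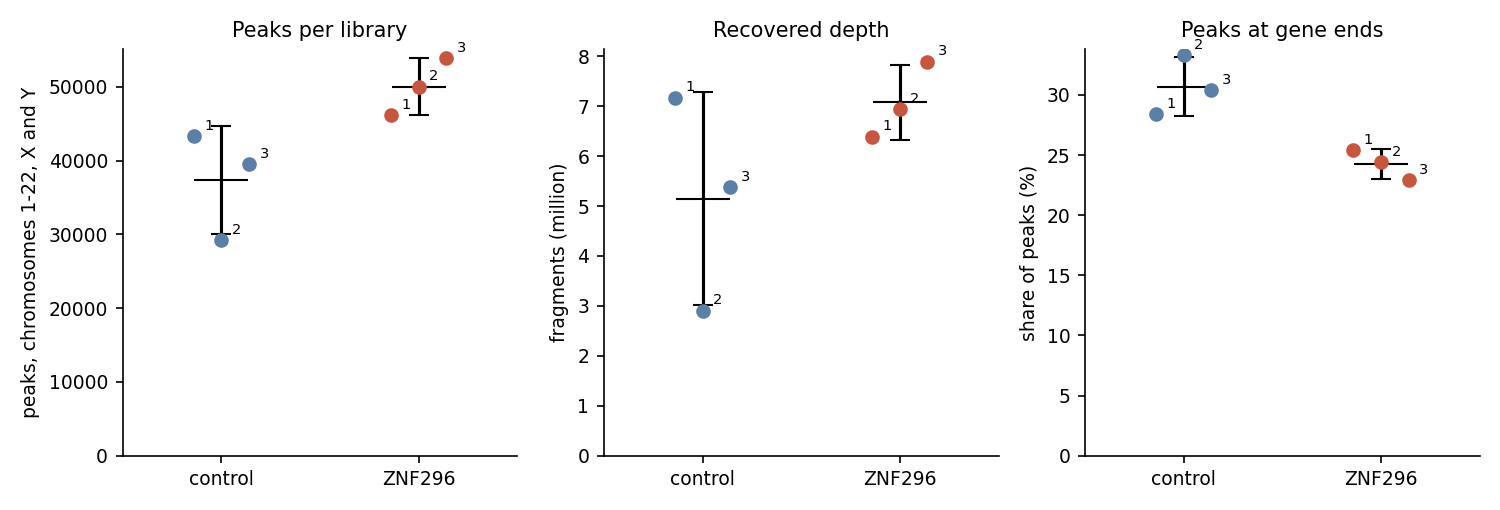
Peaks per library, recovered depth in M fragments, and the share of peaks at gene ends in percent, for the 3 control and 3 ZNF296 libraries (points, numbered by replicate; horizontal line, mean; bars, SD). Peak numbers and gene-end shares do not overlap between the groups, while depths do, with control replicate 2 at 2.91 M fragments.

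The next comparison concerned regions found in all libraries of one group and none of the other. The highest-ranking ZNF296-only region, by q-value within each list, was the one inside ZNF296. The next ones lay on chromosome 21 at 8448732 to 8449273 (fold enrichment 2.60 to 3.12 over the 3 libraries) and 8404530 to 8405077 (2.66 to 2.88), near annotated copies of the 45S ribosomal RNA gene and with no protein-coding gene within 100000 bases. Their fold enrichments were far below those of the other regions named here, and reads there can be shared between copies, so their position is uncertain. They were followed by a region inside TMEM92 (chromosome 17, 50279921 to 50280669, fold enrichment 10.5 to 11.1) and one inside MAJIN, a meiotic telomere gene (chromosome 11, 64970741 to 64971160, 14.2 to 17.6). The highest-ranking control-only region lay on chromosome 17 at 17028033 to 17028735, nearest to MPRIP (fold enrichment 17.5 to 18.8). It was followed by regions at C19orf33 and YIF1B (chromosome 19, 38304793 to 38305416, 8.10 to 8.32), in the noncoding gene LINC01843 near JADE2 (chromosome 5, 134506021 to 134506732, 12.04 to 14.05), near SDC1, which encodes the proteoglycan syndecan-1 (chromosome 2, 20179602 to 20180500, 11.5 to 14.2), and inside TMEM230 (chromosome 20, 5065718 to 5066350, 16.4 to 18.6). All 10 of these regions kept their full split between the groups at matched depth.

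Merging the 6 lists gave 84740 regions, of which 18511 had a peak in all 6 libraries and 30934 in 1 library. There were 5162 ZNF296-only and 1511 control-only regions, so 77.4% of the 6673 group-specific regions were ZNF296-only. The balance depended on scaling. At matched depth there were 3103 ZNF296-only and 1860 control-only regions (62.5% ZNF296-only), and with the same number of peaks taken from each list there were 2596 and 2586 (50.1%). Without control replicate 2 the counts were 5484 and 3290 (62.5%). There a control-only region needs a peak in fewer libraries than a ZNF296-only region, so these counts follow unlike rules. No test was made per region, because presence in 3 libraries against 3 cannot give p below 0.1.

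**Figure D3:**
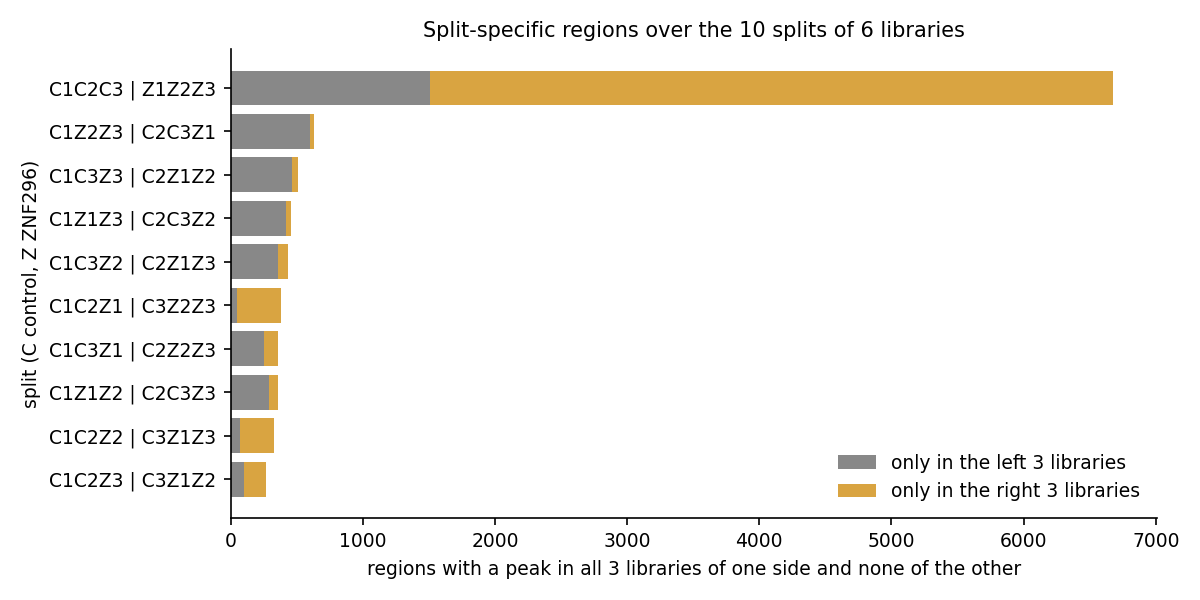
Number of regions with a peak in all 3 libraries of one side and in none of the other (x axis), for each of the 10 ways to split the 6 libraries into 3 and 3 (y axis; C, control; Z, ZNF296). The split by group gave 6673 regions and the highest other split 633.

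ZNF296-only regions lay at gene ends less often than regions found in exactly 3 libraries of mixed groups. The share was 6.72% (exact 95% interval 6.05 to 7.44, 5162 regions) against 12.2% (11.2 to 13.3, 3733 regions), with p = 1.03e-18 by Fisher's exact test, two-sided. Mixed regions had weaker peaks (median of the lowest within-list percentile 13.6, against 28.8), and with mixed regions reweighted to the ranks of the ZNF296-only regions the difference went from -5.49 to -3.29 percentage points (95% bootstrap interval -4.86 to -1.93). Control-only regions, at 12.7% (11.1 to 14.5, 1511 regions), did not differ detectably from the mixed regions (Fisher's exact test, two-sided, p = 0.643), but this depended on the setting. Their share was higher than that of mixed regions without any 1 of the control libraries (by 5.73 percentage points without control replicate 2, Fisher's exact p = 5.4e-21) and with windows of 2500 bases (by 3.34, Fisher's exact p = 0.00572), and lower when peaks had to cover 50% of a region (-6.1, Fisher's exact p = 4.05e-07). The shares of ZNF296-only and control-only regions differed (odds ratio 0.495, Fisher's exact test, two-sided, p = 8.61e-13). Regions are not replicates, and these tests describe the regions of these 6 libraries. The median distance to the nearest gene end was 25.98 kb for ZNF296-only, 15.8 kb for control-only and 20.7 kb for mixed regions, and 3.74 kb for regions found in all 6 libraries, of which 44.8% lay at gene ends.

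**Figure D4:**
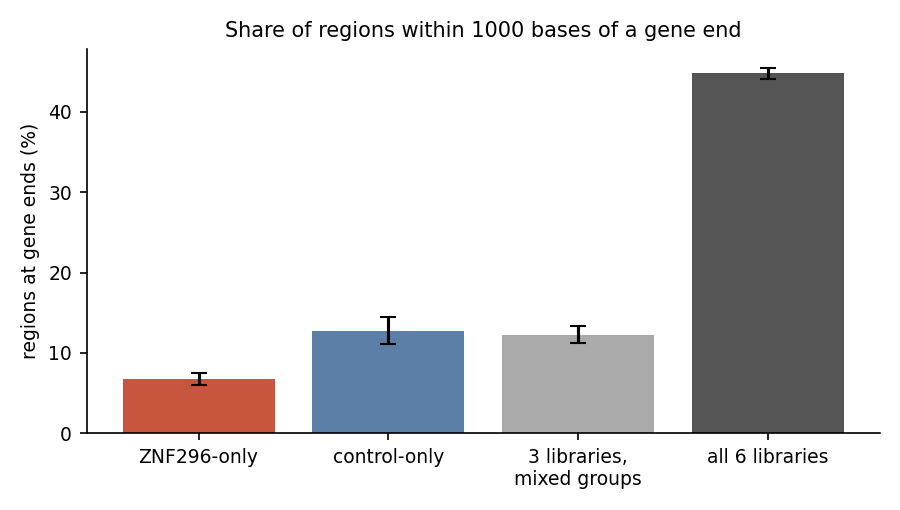
Share of regions overlapping a window of 1000 bases on each side of a protein-coding gene end (percent), by class of region; error bars are exact 95% binomial intervals over regions. ZNF296-only regions stand lowest, at 6.72%, and regions found in all 6 libraries highest, at 44.8%.

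At the level of genes, 196 protein-coding genes had a gene-end peak in all ZNF296 libraries and no control library, and 104 had the opposite. Genes of the preset lists with ZNF296-only gene ends were SLC2A3 (a glucose transporter), IFI16 (a sensor of nuclear and cytosolic DNA), IL1B (the cytokine interleukin-1 beta), CD80 (a ligand of CD28 and CTLA-4), ROBO4 (an endothelial receptor), MX2 (an interferon-induced antiviral GTPase), EPCAM (an epithelial adhesion molecule), CLEC2B (a ligand of the NK cell receptor NKp80) and NANOG (a pluripotency factor). Those with control-only gene ends were EGR2 (an immediate early transcription factor), PFKL (liver phosphofructokinase), CD276 (the checkpoint ligand B7-H3) and TXNRD1 (thioredoxin reductase, an NRF2 target). At matched depth the ZNF296 peak was left in 2 of 3 libraries at IL1B, MX2 and CLEC2B and in 1 of 3 at EPCAM and NANOG, whereas SLC2A3, IFI16, CD80, ROBO4 and the 4 control-only genes kept their full split. The weakest of these peaks, at NANOG, ranked as low as the 1.37th percentile of its list.

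The 10 ZNF296-only genes with the highest-ranking peaks were CLEC19A, PABPC4, SBSN, C2orf78, KIF21B, HCAR3, CRACR2B, LIM2, S100A12 and CFAP73. CLEC19A had fold enrichments of 12.9 to 16.5 and PABPC4, a cytoplasmic poly(A)-binding protein gene, of 13.14 to 14.99. S100A12, which encodes a calcium-binding protein of myeloid cells, had 10.6 to 13.2. The 10 control-only genes were CCDC201, FLII, SHISA4, WNT8B, GRAMD1A, SLC2A4RG, S100P, EGR2, MMP17 and S100A3. SHISA4 had fold enrichments of 11.3 to 12.7, the calcium-binding protein gene S100P 9.62 to 14.9, and EGR2 7.48 to 9.75. These 20 genes kept their full split at matched depth. Over the 32 named group-specific genes, list members included, the full split was left for 27 at matched depth, 25 with equal numbers of peaks, 21 with windows of 500 bases and 19 with windows of 2500 bases. With the widest windows, EPCAM, EGR2, PFKL, CLEC19A, PABPC4, FLII, WNT8B and S100A3 had gene-end peaks in as many ZNF296 as control libraries.

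The balance of gene ends turned with scaling. As deposited, 65.3% of the 300 group-specific genes were ZNF296-only. At matched depth there were 142 ZNF296-only and 203 control-only genes, and with equal numbers of peaks 130 and 381. Without control replicate 2 there were 213 and 237, but there a control-only gene needs a peak in fewer libraries than a ZNF296-only gene. Leaving out control replicate 1 gave 394 ZNF296-only genes, leaving out ZNF296 replicate 1 gave 303, and leaving out ZNF296 replicate 3 gave 174 control-only genes. Of the genes as deposited, 80 of the 196 ZNF296-only and 79 of the 104 control-only were called again at matched depth. Gene ends of 9488 of 20037 genes had a peak in all 6 libraries and those of 6001 in none.

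**Figure D5:**
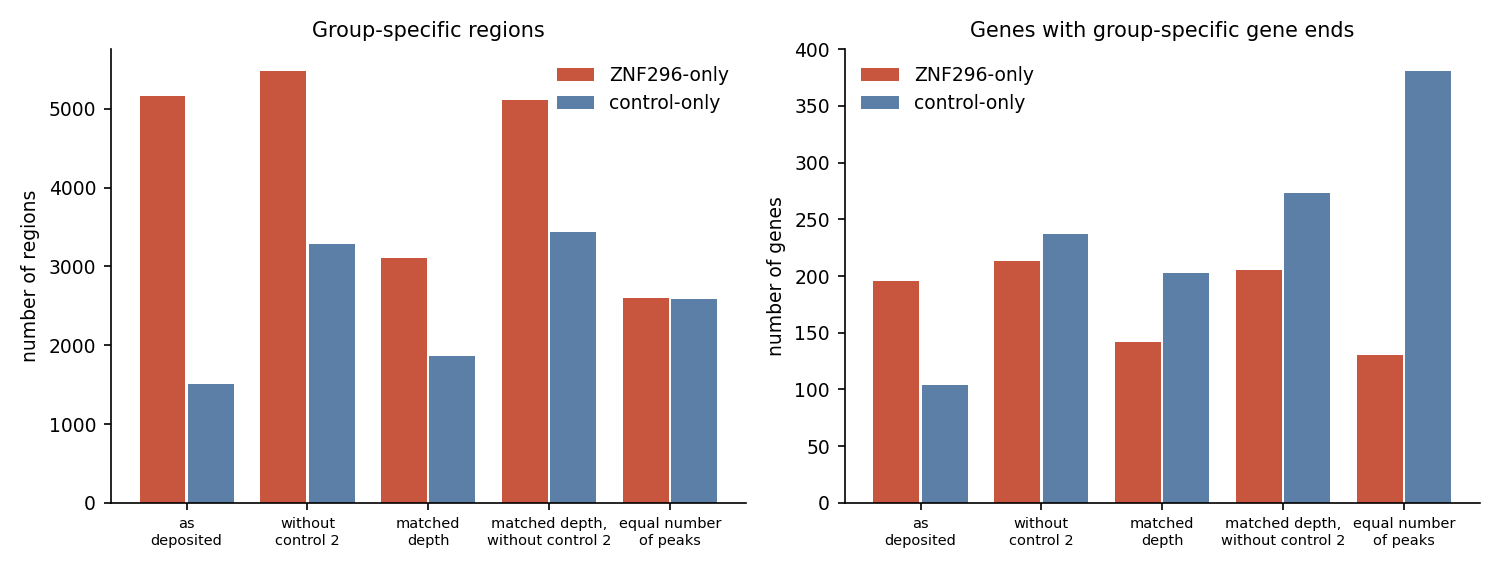
ZNF296-only (red) and control-only (blue) counts of regions (left) and of genes with group-specific gene ends (right) under 5 settings. In the settings without control replicate 2, control-only calls need a peak in fewer libraries than ZNF296-only calls. Regions go from 5162 against 1511 as deposited to 2596 against 2586 with equal numbers of peaks, and genes from 196 against 104 to 130 against 381.

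None of the following immune genes, chosen before the data were examined, had a group-specific gene end. JAK1, JAK2 and IRF1, of the interferon pathway, B2M and NLRC5, of MHC class I presentation, and CGAS, the cytosolic DNA sensor, had a gene-end peak in all 6 libraries. Within-list percentiles did not overlap between groups at B2M (60.2 to 69.77 with ZNF296, 38.23 to 59.03 in control). Nor did they at JAK2 (78.51 to 90.33 with ZNF296, 93.98 to 97.95 in control). They overlapped at JAK1, IRF1, NLRC5 and CGAS. Such percentiles also depend on how many peaks a list holds. CD274, which encodes PD-L1, had one in 3 of 3 ZNF296 libraries and 2 of 3 control libraries, control replicate 2 being the exception. The CD274 peaks ranked at percentiles 82.32 and 87.96 in control replicates 1 and 3. In the ZNF296 libraries they ranked lower, at 36.88 to 56.41, so the count of libraries and the ranks point in opposite directions. STING1, the adaptor downstream of CGAS, had one in 2 of 3 ZNF296 libraries and 0 of 3 control libraries. These STING1 counts were the same at matched depth, in the draw used for single values, and with a −log10 q-value of at least 5. TAP1, the peptide transporter, had one in 2 of 3 ZNF296 and 3 of 3 control libraries. At matched depth, in the thinning draw used for single values, the CGAS peak stayed in 3 of 3 control and 0 of 3 ZNF296 libraries. The TAP1 peak stayed there in 2 of 3 control and 0 of 3 ZNF296 libraries. With a −log10 q-value of at least 5, CGAS had a peak in 2 of 3 libraries of each group. TAP1 then had one in 1 of 3 control and 0 of 3 ZNF296 libraries. As deposited, the CGAS peaks ranked at percentiles 19.1 to 34.4 in control and 14.8 to 33.8 in ZNF296 libraries. The split at CGAS thus depended on the setting. HLA-B, HLA-C and CXCL10 had a gene-end peak in no library, and CCL5 in 1 ZNF296 library. Reads of HLA genes can be placed on alternate contigs of chromosome 6, which these windows do not include.

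None of the 22 preset gene lists passed the tests for a group-wise shift after Benjamini-Hochberg adjustment. The gene-end test can move only on members with a peak in some but not all libraries. Such members numbered 20 of 44 for interferon-stimulated genes, 10 of 26 for MHC class I antigen presentation and 11 of 30 for checkpoint ligands and suppressive factors. A list that did not pass is thus no evidence of equal accessibility. For gene ends, 2 lists had an unadjusted p under 0.05 against 10000 random lists matched on the number of libraries with a peak, two-sided. The list of NRF2 targets and xenobiotic metabolism had 8 members with a peak in more control than ZNF296 libraries and 4 the other way, among 34 measured (permutation p = 0.0084, adjusted p = 0.185). The pluripotency list, whose members include NANOG, had 8 members with a peak in more ZNF296 libraries and 0 the other way, among 24 (permutation p = 0.034, adjusted p = 0.374). Of 44 interferon-stimulated genes, 13 had a peak in more ZNF296 libraries and 5 in more control libraries (permutation, adjusted p = 1). Of 26 genes of MHC class I antigen presentation the counts were 3 and 3, and of 30 checkpoint ligands and suppressive factors 5 and 6 (permutation, adjusted p = 1 for both).

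For regions assigned to their nearest gene, 1 list had an unadjusted p under 0.05. Genes of the NF-kB pathway had 6 ZNF296-only and 7 control-only regions (Fisher's exact test, two-sided, p = 0.0141, adjusted p = 0.309). That is 46.2% ZNF296-only, against 77.4% over all group-specific regions, with or without a gene in reach. The control-only regions were 1 each at RELA, NFKBIA, TNIP1, TRAF1 and LTBR and 2 at TNFAIP2, and the ZNF296-only regions were 1 each at NFKBIZ and IRAK2 and 2 each at IKBKB and TNFAIP2. The gene ends of this list went the other way, with 5 of 31 members having a peak in more ZNF296 and 1 in more control libraries (permutation, adjusted p = 1). Chemokine and cytokine genes had 20 ZNF296-only and 2 control-only regions (Fisher's exact test, adjusted p = 0.614), and checkpoint genes 14 and 8 (adjusted p = 0.61). Among checkpoint genes, PDCD1LG2, which encodes PD-L2, and VSIG4 were each nearest to 2 ZNF296-only regions. NT5E was nearest to 2 ZNF296-only regions and 1 control-only region, and PTGES to 2 control-only regions. Glycolysis and hypoxia genes had 12 and 8 (Fisher's exact test, adjusted p = 0.61); this list alone passed under another setting, in which peaks had to cover at least 50% of a region (12 and 12 regions, adjusted p = 0.0246). Lists of markers of other cell types did not pass either: haematopoietic markers had 5 and 1 regions, fibroblast and endothelial markers 14 and 2, and neuronal genes 9 and 0 (Fisher's exact test, adjusted p = 1, 1 and 0.614).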

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

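Peaks on 7 alternate contigs of the major histocompatibility complex on chromosome 6, which hold further haplotypes of the HLA gene region, entered no comparison above, and they stood higher in every ZNF296 library than in every control library. Their number was 263 ± 47.5 in ZNF296 libraries (222 to 315) and 143 ± 79.0 in control libraries (59 to 216; SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). As a share of all peaks of a library the groups overlapped, at 0.469% to 0.569% and 0.197% to 0.485% (exact two-sided permutation p = 0.2, n = 3 each). At matched depth, a check chosen after the result was seen, the groups were separate in 18 of 20 draws. No sample was tested as an outlier, since the groups hold 3 libraries each.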

How the results depend on the processing

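Matched depth, with all libraries or without 1, and coverage of 50% of a region were chosen after the data were seen. Of 168 values recomputed under alternatives, 27 changed in direction, crossed a threshold or, for counts of regions, genes and lists, moved by more than 1.5 times. Group differences that only changed in size are not among the 27, as for peak number (12658, and 4817 at matched depth), covered length (6.54 Mb, and 2.02 with equal numbers of peaks) and background depth (0.178 fragments per base, and 0.0822 without control replicate 2). The larger number of peaks with ZNF296, the lower share of peaks at gene ends (differences of -7.6 to -2.24 percentage points), the similarity within groups and the lower gene-end share of ZNF296-only regions (-12.6 to -4.77) kept their direction under every alternative run for them. With 3 libraries per group, p-values of group means say nothing about stability. No preset list passed at gene ends under any alternative (lowest adjusted permutation p = 0.0748).

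Counts moved as follows, and where no construction is named the cause was not tested. Equal numbers of peaks gave 2596 ZNF296-only and 2586 control-only regions, and 130 and 381 genes; this setting removes peaks from the longer lists by construction. Matched depth gave 3103 ZNF296-only regions and 203 control-only genes, and without control replicate 2 it gave 3442 control-only regions and 273 control-only genes. A fold enrichment of at least 5 gave 175 control-only genes, and the asymmetric threshold, a subset by construction, 69. Leaving out 1 library at a time gave 5484 to 7990 ZNF296-only regions (highest without ZNF296 replicate 1), 1746 to 3290 control-only regions (highest without control replicate 2), 213 to 394 ZNF296-only genes (highest without control replicate 1) and 117 to 237 control-only genes (highest without control replicate 2); fewer libraries must hold or lack a peak.

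The gene-end share of control-only minus mixed regions was not past the threshold as deposited (0.491 percentage points). It was -1.08 at a −log10 q-value of at least 5, -0.707 with summits, -0.638 with windows of 500 bases, -0.0306 at matched depth and -6.1 (Fisher's exact p = 4.05e-07) with coverage of 50%. It was 3.34 (Fisher's exact p = 0.00572) with windows of 2500 bases, 5.74 (p = 1.34e-20) at matched depth without control replicate 2, and 0.571 to 5.73 with 1 library left out, past the threshold without any 1 control library. The cause was not tested. Coverage of 50% let 1 list, glycolysis and hypoxia, pass for regions.

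Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.00992, -0.00325 and -0.00311. With a replicate block the difference in peak number, 12658, had an exact sign-flip p = 0.25 (n = 3 pairs, the smallest possible), as had that in gene-end share; no call changed. The planned overlap rule of 50% of the region or of the peak is met by every peak, since regions are unions of peaks, so it gave no separate values. The 26 motifs and the exons of ZNF296 were not analysed here. In the simulation, where part of the regions were given lowered pileups, most 4-fold changes were missed, more of them in the control-only direction. Absence of a call is thus no evidence of equal accessibility.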

Other observations

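All tests in this part were chosen after the results they bear on were seen, except those of enrichment and of peak strength.

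ZNF296-only regions gathered near some genes. PPARG, a nuclear receptor of adipogenesis, PRKCH, a protein kinase C gene, RNF216, SPP2, SVIL, which encodes supervillin, and TNC, which encodes the matrix protein tenascin-C, were each the nearest gene to 5 ZNF296-only regions and 0 control-only regions. GLI2, a transcription factor of hedgehog signalling, had 4 and 3. On the control-only side, PLEC, which encodes plectin, had 4 control-only and 0 ZNF296-only regions, and RXRA, the retinoid X receptor alpha gene, and MMP17 had 4 and 1. In all, 30 genes had 4 or more ZNF296-only regions, against a mean of 20.8 when classes were permuted among regions found in exactly 3 libraries (permutation p = 0.0154, one-sided, 10000 draws). The permutation did not keep the distance to gene ends, in which ZNF296-only and mixed regions differed. It therefore cannot separate clustering from location. Among the genes with 5 ZNF296-only regions, merged regions of any class numbered 11 (SPP2) to 27 (PRKCH). Regions near 1 gene may share a broad open domain, so they are not independent, and this clustering is a hypothesis from 1 threshold.

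ZNF296-only regions lay farther from gene ends than control-only regions, with geometric mean distances in a ratio of 1.75. Permuting the classes among these regions gave no difference as large (two-sided permutation p = 1e-05, the smallest that 100000 draws can give). Regions are not replicates, and this describes these libraries. The distances were compared only in the lists as deposited, without matching depth. Every control-only region needs a peak in control replicate 2, the shallowest library. There 33.3% of peaks lay at gene ends, against 28.4% and 30.4% in control replicates 1 and 3, so an effect of depth on the distances was not tested.

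The group split gave 6673 group-specific regions against at most 633 in the other 9 splits, and 300 group-specific gene ends against at most 58. In both cases 1 of 10 splits, the real one, gave a count as large. With 10 splits the share cannot go below 0.1, too few splits for a share under 0.05.

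More regions were ZNF296-only than control-only. After thinning the ZNF296-only share was at least 61.7% in 20 draws with all libraries and at least 59.4% with any 1 library left out (lowest without control replicate 2). This argues against depth as the whole cause only so far as thinning removes the effect of depth. Thinned to the depth of control replicate 2, which held 29254 peaks, control replicates 1 and 3 kept 33502 and 33687, so part of that effect may remain. The draws measure thinning noise only, and with 3 libraries per group the spread between libraries is known only from leaving each out. The share was 77.4% before thinning, so depth may carry part of the imbalance. In the simulation at the recovered depths, 0.781% of unchanged regions were called ZNF296-only and 0.068% control-only. Unequal depth alone can thus give a strong imbalance in this direction. Its size rests on the simulated pileups, so it does not tell how much of the observed imbalance is due to depth. Stronger enrichment is argued against by the summit pileups over the 18511 regions shared by all libraries, whose median per M fragments was 4.82 to 4.90 in ZNF296 and 5.02 to 5.16 in control libraries, a ratio of means of 0.958. A balance of 50.1% with equal numbers of peaks leaves open how much of the excess rests on the longer lists. An effect of ZNF296 on distal sites stays open, untested, since an effect of the vector or its delivery, or any unrecorded difference between the cultures, would follow the same groups.

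The low gene-end share of ZNF296-only regions was not removed by thinning. The difference from mixed regions lay between -9.88 and -7.92 percentage points over 20 draws with all libraries and was at most -6.20 with any 1 left out. This argues against depth so far as thinning removes its effect. Peak strength could carry part of it. With mixed regions reweighted to the same ranks the difference was -3.29 (95% bootstrap interval -4.86 to -1.93), from -5.49 before. The interval leaves out 0 but reaches past the bound of -2 set beforehand for excluding strength, so the question stays open.

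At ZNF296, the local background in every ZNF296 library was at least 25.6 times the library floor, above the highest control value of 13.9. A candidate explanation for the ZNF296-only peak is reads from the introduced reading frame, but this background cannot tell. Spread over 10000 bases, a block with the summit pileup and length of the peak, the most it can add, comes to 16.5 to 21.5. That is at least 1.12 times the 14.4 to 17.7 seen in these libraries. The peak's own reads, whatever their origin, may thus make up most of this background. The edges of the peak differed by 32 bases over the ZNF296 libraries, start and end together. The median was 222 over 5129 ZNF296-only regions, which put this peak at the 1.83rd percentile. Closely repeated edges could come from the introduced reading frame, but regions of the same strength were not compared, so they do not decide it. The raised background as the reason why the control-only peak was missing is argued against: a control pileup scaled to the ZNF296 depths would have passed the threshold over the highest background at the gene in 9 of 9 pairs of libraries (lowest −log10 p-value 19.2). A change of the endogenous gene stays open and was not tested.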
